A study of Mus musculus with 26 samples.

How the data were processed

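ChIP-seq was made from mouse livers at 8 times from 0 to 168 h after removal of 3 of 5 lobes, per the labels' protocols. The 26 samples comprised 8 each for C/EBPalpha, C/EBPbeta and RNA polymerase II (Pol II), 1 for Egr1 at 36 h and 1 mock immunoprecipitation at 0 h. The mock sample was not analysed here, so no value is given over its background. Samples were grouped by the antibody and time in their titles, and 25 files were used. Bowtie 0.12.7, MACS 1.4.1 and the build mm9 are named in the submitters' processing notes, with no role or order. Filters, control libraries and the pooling of the 5 mice per time point are not given in the sources used here. Library batches are not given either, so a batch and a time point cannot be told apart.

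The deposited C/EBP lists held regions with a median width of 17 to 26 bp and a whole-number score from 1 to 1000, scaled within each list, per the file headers a score of a difference or a sum. The caller of these regions is not given in the sources used here. The deposited Egr1 list held MACS peaks, by their names, with a score of 50 or more, a median width of 994 bp and a widest peak of 45732 bp. Scores are the authors' and were used only to rank or filter regions within a list. The deposited Pol II files gave a signed signal per gene, which from its values is summed over the gene body from about 500 bp past the start, less a background. How the authors scaled it between libraries is not given in the sources used here. From 38.4% (168 h) to 50.6% (3 h) of Pol II entries lay below 0, and the signal of the 3 h library alone summed to below 0. The files give no read counts, so depth is unknown and no counting error of a signal can be given. The test planned for Pol II counts was replaced by the one planned for normalized values, since this signal is not a count.

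Of 31804 gene entries, 10871 were not used: 6603 ended before they started and held 0, and others shared a name, had a measured body under 500 bp or lay outside the named nuclear chromosomes. The remaining 20933 genes are called measured. Gene starts were taken from these files, moved back by the 500 bp offset. Of the measured names, 15380 were current symbols and 2614 older names in the RefSeq gene table of the assembly GRCm38.p6, which was used for names and gene lengths only. Overlapping genes cannot be told apart, since ChIP carries no strand.

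Each Pol II value was divided by the gene's measured width. Libraries were rescaled by the median of ratios over 1472 genes above 0.5 in all 8 libraries. This moved the changes against 0 h by 0.26, 0.33, -0.32, 0.41, -0.01, 0.33 and 0.97 on the log2 scale from 3 to 168 h. Changes are therefore relative to these genes. Values below 0 were set to 0 and 0.5 was added before the log2, so changes of low genes are understated. Genes above 0.5 in at least 2 libraries, 4761 in all, were tested with limma 3.58.1 in R 4.3.3. The model was a natural spline with 3 degrees of freedom on the rank of time, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 library per time the spread is that of libraries around a smooth curve, not of replicates. On simulated data with 4761 genes, a smooth rise and fall over the 8 times was planted. The trend test recovered 10 of 100 genes with a planted size of 2 on the log2 scale and 75 of 100 with 4. It called 2 other genes. Recovery of a change confined to single libraries was not simulated.

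Windows were early (3 and 8 h), middle (16 and 24 h), late (36 and 48 h) and final (168 h), each against the single 0 h library. The 23 gene lists, of 398 members with 386 measured, covered plasma proteins, the acute phase, immediate early genes, replication, mitosis, 7 branches of metabolism, ribosome biogenesis, the unfolded protein response, the circadian clock, the C/EBP family, liver transcription factors and 6 other cell types. A list's median change was placed among 10000 random lists matched on mean level in 20 bins. Percentiles below 2.5 or above 97.5 are called outside the central 95%, and describe these libraries only.

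C/EBP lists were compared at 20061 top-scoring regions each, the length of the shortest, and with Egr1 at 9895. Regions sharing 1 bp counted as shared. As a check, bedtools 2.31.1 gave the same counts for the full C/EBPalpha and C/EBPbeta lists of 0 and 36 h. Promoter shares count regions with the centre within 1 kb of a gene start, with Wilson 95% intervals. List lengths and promoter shares were tested with exact sign-flip permutations over 8 pairs, whose smallest p is 0.0078. Sharing at the same time was tested with all 40320 orders of the C/EBPbeta times, whose smallest p is 2.48e-05, and the relation to distance in time likewise. Gained sites were in both lists of a window and not at 0 h, and lost sites at 0 h and in neither list. Sites are region centres joined within 100 bp, a choice made after the data were seen.

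Named genes are those past the trend test with a change of 1 or more in each library of a window, up to 6 members per list by the size of their change, and Cebpa, Cebpb, Egr1 and Ccnd1. Since only Rgs16 passed, genes meeting the size rule alone were added after the data were seen. The lists, tests and most alternatives were fixed before the data were examined. Alternatives were other score limits, overlaps, distances, pseudocounts, filters, baselines and models of time, no rescaling, and each time point left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.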

Results

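The series followed mouse liver regeneration with chromatin immunoprecipitation and sequencing (ChIP-seq), which recovers the DNA bound by a chosen protein. Male C57BL6/J mice of 7 weeks, a common laboratory strain, lost 3 of 5 liver lobes. The removed tissue served as the 0 h sample, and livers were taken at 3, 8, 16, 24, 36, 48 and 168 h. Antibodies were against C/EBPalpha and C/EBPbeta, related transcription factors of hepatocytes, and against RNA polymerase II (Pol II), at all 8 time points, and against the transcription factor Egr1 at 36 h. Each antibody and time point had 1 sample, made from livers of 5 mice, and the labels do not say whether those were pooled before sequencing. There were thus no replicates. The C/EBP lists held 20061 to 54574 regions, the Egr1 list held 9895 peaks, and Pol II was measured over 20933 gene bodies. The files give no read counts, so sequencing depth is unknown. Positions are in the mouse build mm9.

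The lists of C/EBPalpha and C/EBPbeta regions over time asked where each factor was bound during regeneration. Genes of the acute phase response, whose products the liver secretes during inflammation, lay close to regions of both factors throughout. With every list set to its 20061 top-scoring regions, 21 or 22 of the 22 measured genes of this group had a C/EBPalpha region within 10 kb of the start at each time, and 17 to 20 had one within 1 kb. For C/EBPbeta the numbers were 21 or 22 and 17 to 20. Plasma protein genes, such as the fibrinogen genes Fga, Fgb and Fgg, were similar, with 20 to 22 of 22 within 10 kb over the lists of both factors. Regions near active genes were common in general. Of the 4761 genes tested for Pol II, 49.9% to 66.0% had a region within 10 kb in a list. Within 1 kb it was 17.6% to 37.8%. Markers of lymphocytes, stellate cells and fibroblasts had no C/EBP region within 1 kb in any of the 16 lists. These groups hold only 11 lymphocyte and 12 stellate cell and fibroblast genes. Of all measured genes, 8.10% to 19.5% had a region that near in a list, so this need not set the groups apart. Within 10 kb, Tagln of the second group had a region in all 8 full lists of each factor.

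Several of the top-scoring regions lay at or in genes. A C/EBPalpha region on chromosome 4 at 63005471 to 63005496 had the top score at 16 h and lay 117 bp from the start of Orm1, which encodes the acute phase protein orosomucoid. Another on chromosome 4, at 97771070 to 97771095, topped the 3 h list and lay inside the body of Nfia, a transcription factor gene. The top C/EBPbeta region at 3 h was at the same place, 97771062 to 97771087. A C/EBPalpha region on chromosome 2 at 52360534 to 52360559, top at 0 h, lay inside Cacnb4, a calcium channel subunit gene. These 3 C/EBPalpha regions had a region within 100 bp in all 8 C/EBPalpha lists. The highest-scoring C/EBPbeta region at 0 h lay on chromosome 1 at 90175838 to 90175863, 1755 bp from the start of Hjurp, a centromere gene, and was met in 6 of 8 C/EBPbeta lists. Whether these places are exonic or intronic was not analysed here.

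Genes of DNA replication and the G1/S step of the cell cycle had C/EBPbeta regions within 1 kb of the start most often at 36 h. There 13 of 34 had one, at percentile 99.8 of random gene lists of the same Pol II level, and 11 of 34 had one at 3 h, at percentile 97.0. At 0 h the number was 3 and at 24 h it was 4. For G2/M and mitosis genes it was 10 of 30 at 36 h, at percentile 99.3, 9 at 3 h and 1 at 24 h. C/EBPbeta regions lay near gene starts in general at those times, with 4079 measured genes within 1 kb at 3 h and 3829 at 36 h against 1845 to 2761 at the other times. Of the genes tested for Pol II, 37.8% had one at 3 h and 35.3% at 36 h, though only 6 replication and 7 mitosis genes were tested. Such percentiles were computed for all 23 gene lists, 16 region lists and both distances, with no correction for their number. With C/EBPalpha the replication genes numbered 4 to 7 of 34 over the 8 lists.

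**Figure D1:**
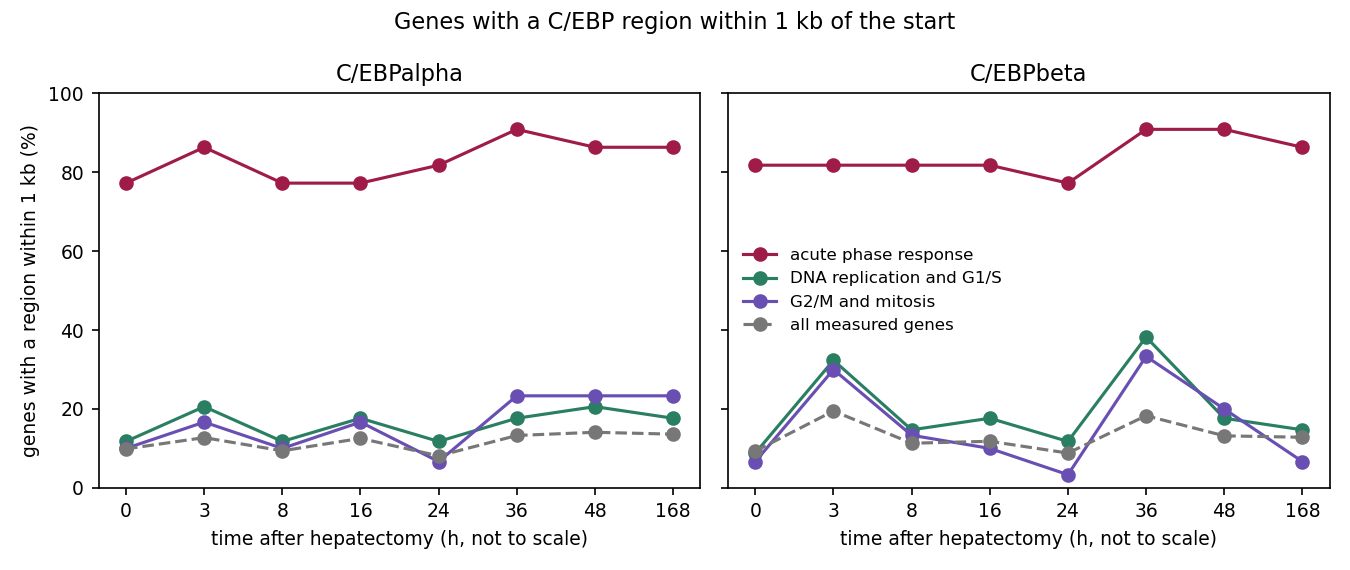
Percent of genes with a C/EBP region within 1 kb of the start (y axis) at each time after hepatectomy (x axis, h), for the 20061 top-scoring regions of each C/EBPalpha (left) and C/EBPbeta (right) list. In the lines for 3 gene lists and all 20933 measured genes, the replication genes reach 38.2% at 36 h for C/EBPbeta, against 18.3% of all measured genes. The share of genes tested for Pol II, not drawn, was 35.3%, and 6 of the 34 replication genes were tested.

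List lengths differed between times. C/EBPalpha regions numbered 29383, 31003, 31267, 28009, 29847, 27061, 20061 and 25972 from 0 to 168 h. C/EBPbeta regions numbered 54574, 35256, 36258, 28720, 34098, 31658, 20608 and 25781. The share of regions within 1 kb of a gene start was 17.4% and 17.1% in the C/EBPbeta lists of 3 and 36 h, and 7.54% to 13.4% in the other C/EBPbeta lists. In the C/EBPalpha lists it was 8.16% to 14.4%. The 95% Wilson intervals of these shares reached at most 0.486 percentage points to either side, and cover counting error only.

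**Figure D2:**
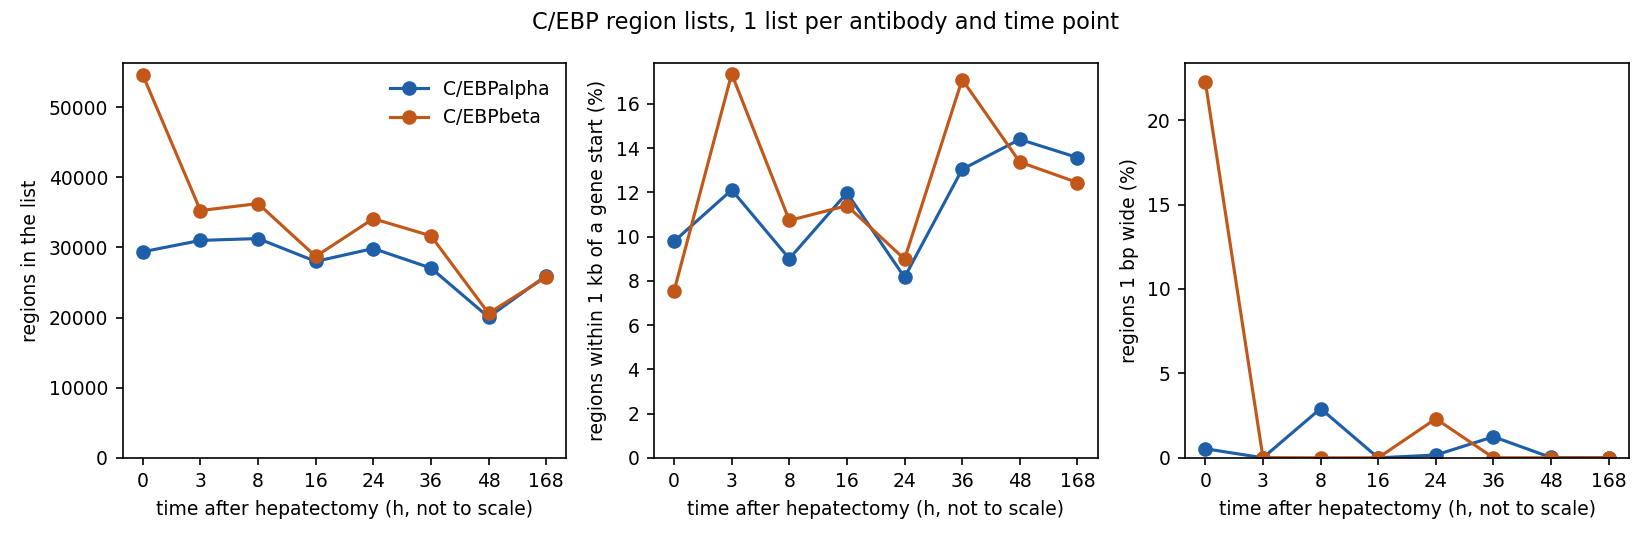
Number of regions, percent of regions within 1 kb of a gene start and percent of regions 1 bp wide (y axes) against time after hepatectomy (x axes, h), with 1 point per list of C/EBPalpha (blue) and C/EBPbeta (orange). The C/EBPbeta list of 0 h has 54574 regions, 22.3% of them 1 bp wide.

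The lengths of the C/EBPbeta and C/EBPalpha lists were compared over the 8 time points as pairs. List length depends on depth and enrichment as well as on binding. Depth is unknown, so the comparison cannot tell whether C/EBPbeta occupied more places. C/EBPbeta lists were longer in 7 of 8 pairs, by 0.22 on the log2 scale on average (exact two-sided sign-flip permutation p = 0.0156, adjusted 0.0312 over 2 comparisons). Without the 0 h pair the difference was 0.13 (exact permutation p = 0.0312). Without pairing the exact permutation p was 0.202, and among regions scoring at least 100 the value was -0.17 (exact p = 0.586), but scores are scaled within each list, with medians of 15 to 57, so this limit does not compare list lengths. Genomic sites found in 2 or more C/EBPbeta lists and no C/EBPalpha list numbered 4834, and 19.1% of them lay within 1 kb of a gene start. Sites in 2 or more C/EBPalpha lists and no C/EBPbeta list numbered 1351, with 6.81% within 1 kb. Both numbers come from full lists of unequal length, on average 33369 regions for C/EBPbeta and 27825 for C/EBPalpha. The mean promoter share of the lists did not differ by the test, at 12.4% for C/EBPbeta and 11.5% for C/EBPalpha, higher for C/EBPbeta in 4 of 8 pairs (exact sign-flip permutation p = 0.398, adjusted 0.398).

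Numbers of regions of the 2 factors were compared across the 8 times, with 2 such relations computed. Pearson's r was 0.640 (exact permutation p = 0.117, adjusted 0.117) and Spearman's rho 0.833 (exact permutation p = 0.0154). Without the 48 and 168 h times r was 0.242 (exact permutation p = 0.685), so Pearson's r rested on them. Spearman's rho was not computed without them. For promoter shares r was 0.655 (exact permutation p = 0.0834, adjusted 0.117) and rho 0.714 (exact permutation p = 0.0576), and r was 0.550 without 8 and 24 h.

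C/EBPalpha and C/EBPbeta regions of the same time coincided more than regions of different times. Of the 20061 top-scoring regions, 41.5% on average were shared between the factors at the same time and 29.8% at different times (exact permutation of the C/EBPbeta times, two-sided p = 0.000223). Whether the libraries of both factors at a time came from the same chromatin is not given in the sources used here. At 16 h 61.7% were shared and at 24 h 49.1%, against 26.05% at 0 h and 23.4% at 36 h. By centres within 100 bp these shares were 77.2%, 67.2%, 54.7% and 62.5%, and 24 h then lay below 48 and 168 h (73.9% and 75.1%). The C/EBPalpha list shared most with the C/EBPbeta list of its own time in 4 of 8 cases by overlap and in 6 of 8 by centres. The 3 h C/EBPalpha list shared 52.7% with C/EBPbeta at 8 h and 40.0% with C/EBPbeta at 3 h.

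**Figure D3:**
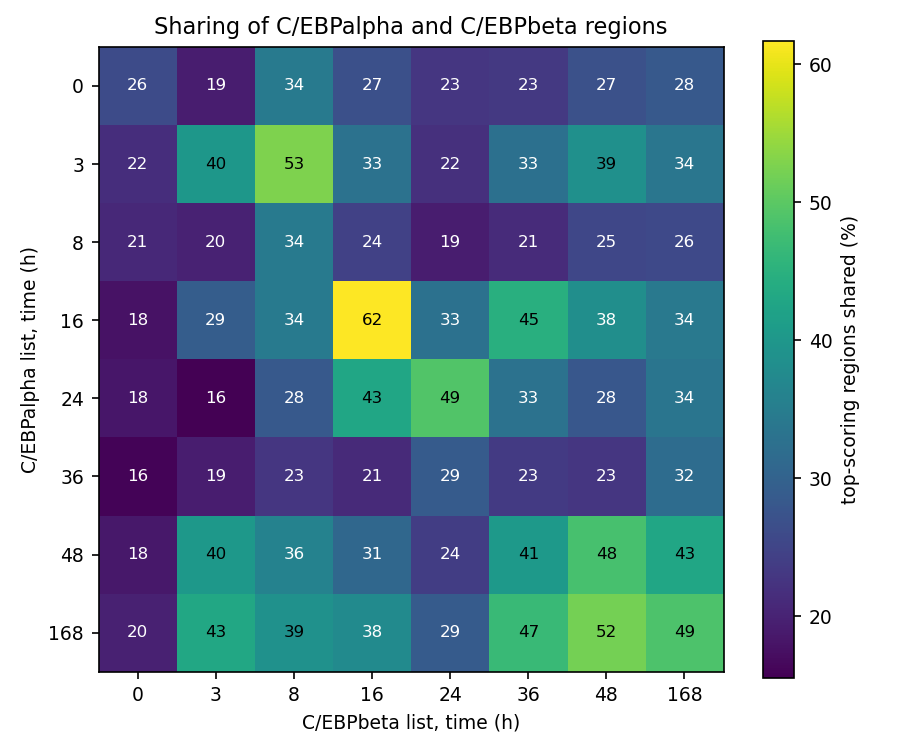
Percent of the 20061 top-scoring regions shared by at least 1 bp between a C/EBPalpha list (y axis, h) and a C/EBPbeta list (x axis, h). Each cell is 1 pair of lists, from 15.5% to 61.7%, and same-time pairs lie on the diagonal.

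Over all 16 lists, centres within 100 bp of the next were joined into 105171 sites. Of these 7724 were in all 16 lists, 12.2% of which lay within 1 kb of a gene start. Sites in 1 list alone numbered 48961, and 23304 of them belonged to the 0 h C/EBPbeta list.

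The time order of the lists was asked with a rank correlation of sharing against distance in time. Neither factor's regions were detectably more alike at neighbouring times, with rho -0.11 for C/EBPalpha (exact permutation p = 0.587) and -0.21 for C/EBPbeta (exact permutation p = 0.293). Without the 3 h list the C/EBPbeta value was -0.49 (exact permutation p = 0.0421). Of the 20061 top-scoring 0 h C/EBPalpha regions, 21.5% (36 h) to 31.9% (3 h) were met by 1 bp or more in the top of a later list. For C/EBPbeta this was 13.8% at 3 h and 23.8% at 8 h, the lowest and highest. Since the median region was only 17 to 26 bp wide, centres within 100 bp gave larger shares, with averages over later times of 57.7% and 46.6%. Of the 1000 top-scoring 0 h C/EBPalpha regions, 90.5% (36 h) to 97.2% (3 h) had a centre within 100 bp in a full later list. For C/EBPbeta this was 87.1% (3 h) to 96.1% (8 h). The low shares above thus need not mean lost binding.

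Pol II over the genes of the factors themselves came first among the genes followed. Cebpa, on chromosome 7 at 35904822 to 35906945, had 93.2 signal units per bp at 0 h and 9.02 to 23.2 at all later times. Cebpb, on chromosome 2 at 167514967 to 167515887, had 56.5 at 0 h, 381 at 3 h, 66.2 at 8 h and 13.9 at 168 h. Egr1, an immediate early gene, had 19.6 at 0 h, 43.4 at 3 h and 3.32 at 24 h. Ccnd1, which encodes cyclin D1, had 3.28 at 0 h, 0.914 at 3 h and 4.49 at 168 h. All comparisons with 0 h shared the single 0 h library.

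A trend over the 8 libraries was tested in 4761 genes with limma, which found 1 gene at an adjusted p under 0.05. Rgs16, a regulator of G protein signalling on chromosome 1 at 155587978 to 155592594, fell from 49.7 signal units per bp at 0 h to 12.7 at 3 h and 0.869 at 8 h. It lay below 0 from 16 to 48 h and was at 1.51 at 168 h (adjusted p = 0.0296, limma F test on a spline). The call ended without the 8, 16, 24 or 36 h library, with smallest adjusted p of limma from 0.107 to 0.131, and with no filter (0.282) or a pseudocount of 0.05 (0.069). Without the 0 h library 6 genes passed, led by Apoa4. At an unadjusted p under 0.05 there were 465 genes. Adjusted over the list alone, 1 gene each passed in 6 fixed lists: Maff, an immediate early gene, Tk1, thymidine kinase, Cebpa, Foxa2, a liver transcription factor, Ecm1 and Lck. Only 3 genes of the C/EBP list, 2 stellate cell markers and 1 lymphocyte marker were testable there, and none of the 6 passed over all genes.

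**Figure D4:**
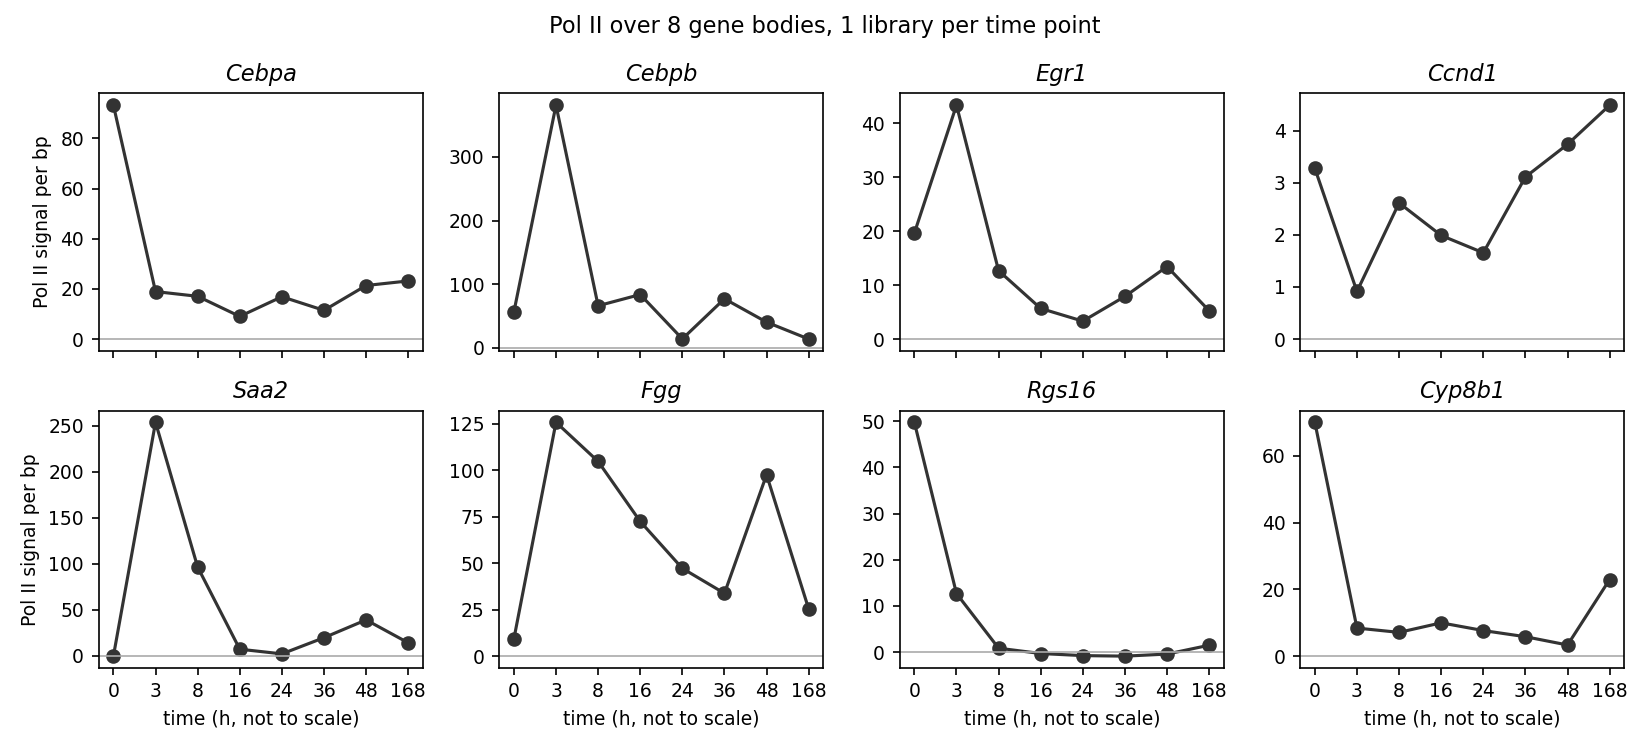
Background-subtracted Pol II signal per bp (y axes, rescaled between libraries) over 8 gene bodies against time after hepatectomy (x axes, h), 1 point per library, grey line at 0. Cebpb reaches 381 and Saa2 254 at 3 h, while Cebpa is at 93.2 at 0 h.

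Changes of gene groups against 0 h were placed among 10000 random lists matched on mean Pol II level. Of the 23 lists in 4 windows, 24 of 92 medians lay outside the central 95% of random lists, 16 of them higher and 8 lower, where chance gives 4.6. No list had a replicate check. Early, at 3 and 8 h, the acute phase genes had a median log2 change of 3.15 (percentile 100), and 19 of 22 were higher by 1 or more. At 3 h alone the median was 4.23. Saa2 and Saa1, serum amyloid genes of high sequence similarity, were below 0 at 0 h and at 254 and 212 at 3 h. Lcn2, lipocalin 2, was below 0 at 0 h and at 326 at 3 h. Socs3, a brake on cytokine signalling, was 4.98 higher on the log2 scale in the early window and Orm1 4.92 higher. The medians were 1.90, 2.05 and 1.73 in the middle, late and final windows, each at percentile 100.

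Plasma protein genes were higher by 0.47 early (percentile 94.97, inside the central range), and by 0.46, 0.52 and 0.74 in the middle, late and final windows (percentiles 97.8, 98.6 and 99.99). The members differed. Fga, Fgg and Fgb were 3.57, 3.56 and 3.13 higher early, while Apoa2, an apolipoprotein gene, was 2.43 lower, from 82.9 at 0 h to 7.87 at 3 h. Without rescaling between libraries the final median of the group was -0.15 (percentile 99.95). In the 16 and 36 h libraries alone the medians were inside the central range, at 0.30 (percentile 88.2) and 0.07 (percentile 60.9).

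Immediate early genes had a median of 1.12 at 3 h (percentile 100), where 12 of 23 were higher by 1 or more. The 8 h median was -0.02 (percentile 28.2) and that of the early window 0.25 (percentile 94.4), both inside the central range. Gadd45g, a stress gene, was at 9.22 at 0 h and 701 at 3 h. In the middle, late and final windows the group was lower than random lists, with medians of -0.65, -0.36 and -0.70 (percentiles 0.040, 1.29 and 0.385). Jun was at 46.8 at 0 h, 7.99 at 8 h and below 0 at 24 and 168 h, and Jund at 40.9 at 0 h and 4.71 at 168 h. At 48 h alone the group lay inside the central range, at -0.23 (percentile 5.75), and so did the final median without rescaling.

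Drug metabolism genes were lower early, with a median of -0.91 (percentile 0.050) and 8 of 18 lower by 1 or more. At 3 h the median was -1.41 and 12 of 18 were lower by 1 or more, and at 8 h alone it was -0.37, inside the central range (percentile 3.82). At 16 h alone the median was -0.47, outside that range (percentile 1.10). The 3 h library stood apart: its deposited signal summed to -16276217 over all entries, against at least 32639618 in each other library, and 50.6% of entries were below 0, against at most 44.3%. With the background level set per library the 3 h median was -1.34 (percentile 0.0). Gsta3, a glutathione transferase gene, was at 11.6 at 0 h, 0.413 at 3 h and 14.9 at 168 h. Cyp1a2, which overlaps Cyp1a1 in the files, was at 9.96 at 0 h and below 0 at 3 h. Cyp3a25 was at 3.29 at 0 h, below 0 at 3 h and at 7.00 at 168 h. In the final window the group was higher, by 0.43 (percentile 97.9), but at -0.23 without rescaling (percentile 94.8), and inside the central range against lists matched on gene length too.

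Bile acid, cholesterol synthesis and glucose genes had their lowest medians in the same 3 h library, whose signal summed to below 0. Bile acid genes were at -0.62 early (percentile 2.73, inside the central range) and -0.93 at 3 h (percentile 1.18). Cyp8b1, a bile acid synthesis enzyme gene, was at 70.1 at 0 h, 8.41 at 3 h and 3.34 at 48 h. Cyp7a1, the rate-limiting enzyme of that pathway, was at 5.64 at 0 h, below 0 at 3 h and at 25.03 at 168 h. Cholesterol synthesis genes were at -0.97 at 3 h (percentile 0.10), and higher in the late and final windows by 0.64 and 0.83 (percentiles 99.75 and 99.94), though not at 48 h alone (percentile 97.2). Glucose and glycogen genes were at -0.80 at 3 h (percentile 1.57). At 8 h alone the 3 groups were inside the central range, at -0.23, 0.40 and 0.08 in the order named. With the background level set per library the 3 h medians were -0.89, -0.65 and -0.77 (percentiles 0.465, 0.330 and 0.90). The fall of the glucose and glycogen genes was not confined to 3 h. They also lay below the central range at 16 h (-0.65, percentile 0.44) and 36 h (-0.54, percentile 0.82), and inside it at 24 and 48 h (percentiles 18.5 and 26.3). Fdps, of the sterol pathway, was at 1.73 at 0 h, 0.348 at 3 h and 8.93 at 16 h.

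In the final window glucose and glycogen genes were higher by 0.64 (percentile 99.5) and urea cycle and amino acid genes by 0.81 (percentile 99.95). Without rescaling their medians turned to -0.25 (percentile 95.2) and -0.06 (percentile 99.94). The 168 h library was the one most moved by rescaling, by 0.97 on the log2 scale against 0 h. G6pc, glucose 6-phosphatase, was at 10.9 at 0 h and 46.9 at 168 h. Cps1, which starts the urea cycle, was at 2.07 at 0 h, 20.3 at 24 h and 11.5 at 168 h. Fatty acid synthesis and oxidation genes stayed inside the central range in all 4 windows, with medians from -0.13 to 0.27.

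DNA replication genes were higher in the late window, by 0.46 (percentile 100), which came from the 36 h library. At 36 h the median was 0.88 and 11 of 34 were higher by 1 or more, and at 48 h the median was 0.00. Rrm2, a ribonucleotide reductase subunit, was at 0.106 at 0 h, 3.05 at 36 h and 0.216 at 48 h. Pcna, the replication clamp, was below 0 at 0 h, at 1.29 at 36 h and at 0.436 at 48 h. G2/M and mitosis genes had a late median of 0.18 (percentile 100), 0.26 at 36 h and 0.06 at 48 h. The gene the files call Cdc2a, now Cdk1, the mitotic kinase, was near 0 at 0 h, at 1.26 at 36 h and at 0.850 at 48 h. These are low signals, close to the filter of 0.5, and 6 replication and 7 mitosis genes passed it. With values below 0 set to 0, a median of 0.00 lay near percentile 50 for both groups. The mitosis median of 0.06 at 48 h was already at percentile 100. For these 2 groups percentile 100 thus shows little more than a median above 0.

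**Figure D5:**
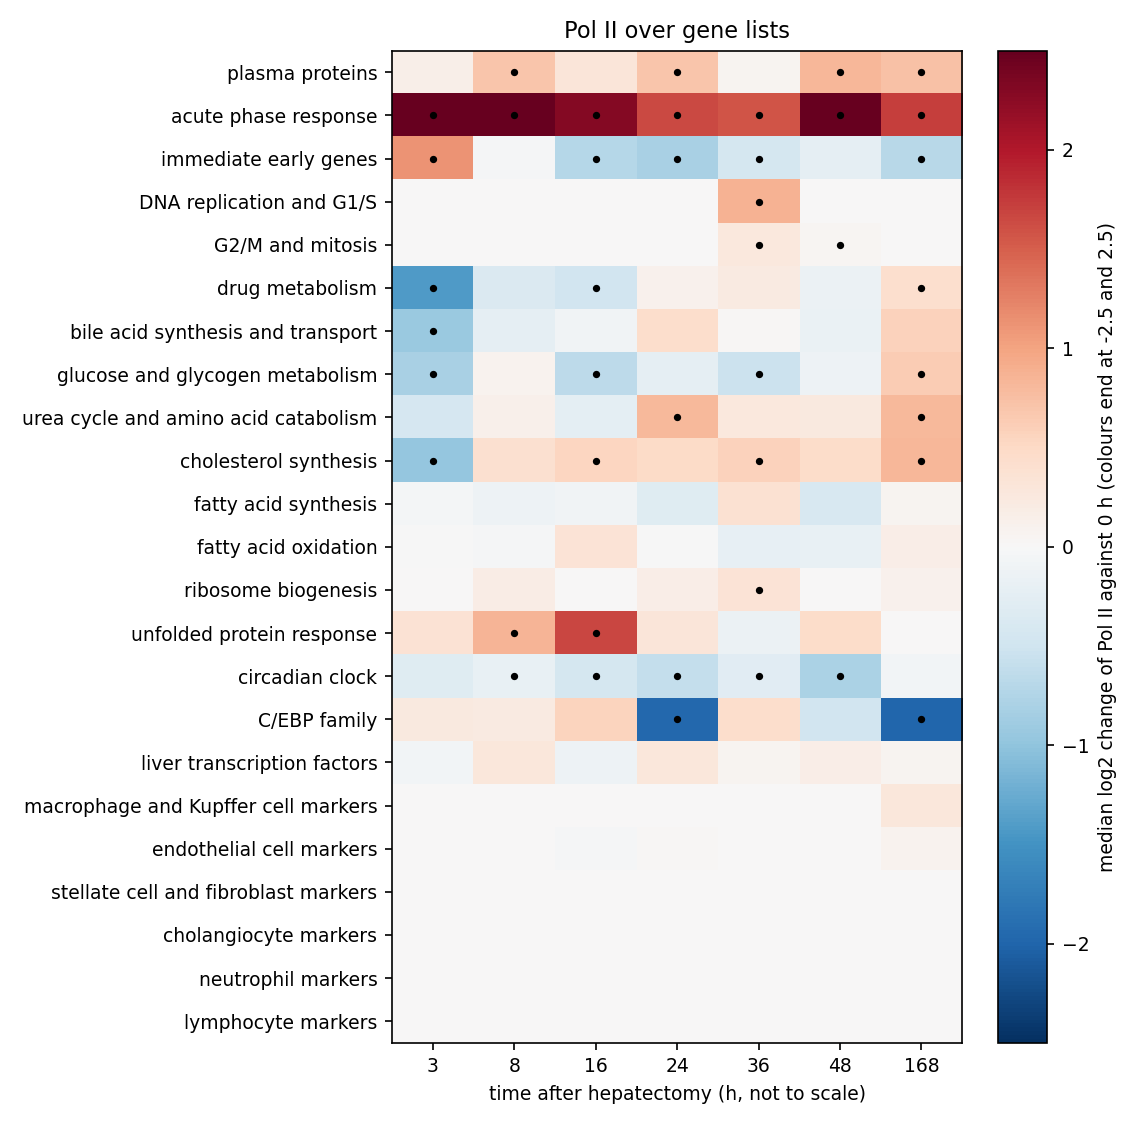
Median log2 change of Pol II against 0 h (colour, ending at -2.5 and 2.5) of 23 gene lists (y axis) at each later time (x axis, h), with a dot where the median lies outside the central 95% of 10000 random lists. Acute phase genes are higher at all 7 times, by 4.23 at 3 h, and drug metabolism genes are lowest at 3 h, at -1.41.

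Markers of macrophages and endothelial cells had medians of 0.00 early, and from 0.00 to 0.29 in the other windows, all inside the central range, and 9 of 13 and 7 of 13 of them passed the filter. For other cells of the liver too few genes carried signal to show a shift: 2 of 12 stellate cell and fibroblast, 0 of 7 cholangiocyte, 1 of 9 neutrophil and 1 of 11 lymphocyte markers passed the filter, and with values below 0 set to 0 their medians were 0.00 in every window. Liver transcription factor genes were also inside the central range, with medians of 0.04 to 0.15, as were ribosome biogenesis genes, at 0.11 to 0.22, of which 4 of 20 passed the filter. The early median of the ribosome biogenesis genes lay just inside the range (percentile 97.49). At 36 h alone their median was 0.35, outside it (percentile 99.8). Of the C/EBP family, 3 genes were measured and the final median of -1.98 (percentile 1.25) was that of Cebpb, next to -1.99 for Cebpa and 1.27 for Cebpg.

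By size alone, a rule applied after only 1 gene had passed the trend test, 294 of 2381 genes at or above the median level were higher by 1 or more in both early libraries and 196 lower. The numbers higher and lower were 273 and 150 in the middle window and 307 and 178 in the late one. In the final window, of 1 library, more were lower (509) than higher (355). Early genes outside the lists included Serpina3n, a protease inhibitor of the acute phase, at 3.43 at 0 h and 150 at 3 h. Inmt, a methyltransferase gene, was at 41.7 at 0 h and below 0 at 3 h, Acaa1b, a peroxisomal thiolase gene, at 30.4 and 0.0872, and Apoe at 156 and 4.50. In the late window H2afx, a histone variant gene, was below 0 at 0 h and at 27.5 at 36 h.

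Egr1 peaks at 36 h lay near genes of some groups of hepatocyte function more often than near random lists of genes, but not of others. Of all Egr1 peaks 24.2% were within 10 kb of a start, which is a share of peaks and not of genes. Of the drug metabolism genes 15 of 18 had an Egr1 peak within 10 kb of the start, among them Cyp2e1 and Cyp3a11 (percentile 100 of random lists). So had 14 of 22 acute phase genes (percentile 100), 13 of 22 plasma protein genes, Alb among them (percentile 100), 9 of 15 bile acid genes (percentile 99.9) and 7 of 16 circadian genes (percentile 99.5). Neighbouring genes, such as Saa1 and Saa2, can share a peak but were counted singly, and the random lists were not matched for this. These percentiles may therefore be too high. Inside the central range were 5 of 14 glucose (percentile 88.25), 6 of 18 urea cycle (79.85) and 7 of 22 cholesterol synthesis genes (91.8). So were 3 of 15 fatty acid synthesis (53.1), 5 of 19 fatty acid oxidation (78.9) and 6 of 14 liver transcription factor genes (94.25). Replication genes had 6 of 34 (percentile 89.2). Macrophage, stellate, cholangiocyte, neutrophil and lymphocyte markers had none, also inside the range (percentiles 5.40 to 32.3). Egr1 itself had a peak within 10 kb, and Cebpa and Cebpb did not.

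The question of whether Egr1 peaks met the C/EBP regions of 36 h in particular was answered by ranks. The 9895 top-scoring C/EBPalpha regions of 36 h overlapped 25.7% of Egr1 peaks, rank 6 of the 8 times, and those of C/EBPbeta 22.8%, rank 7 of 8. In full lists the values were 42.5% and 43.4%. Any C/EBP list met 60.2% of Egr1 peaks, and 6.56% after the peaks were moved by 200 kb. Only 4.54% of Egr1 peaks lay within 1 kb of a gene start (Wilson 95% interval 4.14% to 4.97%), below all 16 C/EBP lists. The top-scoring Egr1 peak, on chromosome 12 at 55819456 to 55820831, lay in no measured gene, 23284 bp from the start of Eapp.

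Pol II near regions that came or went was compared for each factor and window. Genes within 10 kb of C/EBPalpha regions lost early had a median early log2 change of -0.17 (902 genes, percentile 0.0), and those near gained regions 0.10 (766 genes, percentile 99.2). In the middle window genes near gained C/EBPalpha regions were at 0.27 (549 genes, percentile 100), where all tested genes had a median of 0.12, and those near lost regions at -0.01 (percentile 0.0). For C/EBPbeta the early values were -0.06 (2332 genes, percentile 0.0) and 0.08 (1316 genes, percentile 99.7), and the middle values 0.06 near lost regions (percentile 0.345) and 0.16 near gained ones (percentile 94.7, inside the central range). The lost C/EBPbeta sets, of 29096 sites early to 35743 in the final window, all hold the 23304 sites found in the 0 h C/EBPbeta list alone. That list stood apart in length and region width, so these sets need not reflect lost binding. In the late window gained regions did not go with higher Pol II. Genes near gained and lost C/EBPalpha regions were at 0.02 (percentile 6.75) and 0.04 (percentile 2.48), and those of C/EBPbeta at 0.06 and 0.07 (percentiles 25.5 and 4.99), where all tested genes had 0.10. The late call near lost C/EBPalpha regions ended under all 4 alternatives, and within 50 kb gained C/EBPalpha regions gave percentile 0.21. In the final window the order was opposite, with 0.17 near lost and -0.04 near gained C/EBPalpha regions, and 0.07 and -0.07 for C/EBPbeta. Of the 16 sets, 12 lay outside the central 95%, against 3 within 1 kb and 5 among regions scoring at least 100. The early calls near gained regions ended within 50 kb, within 1 kb and with either library of the window (percentiles 93.3, 82.0 and 89.6 for C/EBPalpha, 89.4, 28.5 and 93.0 for C/EBPbeta), and for C/EBPbeta at scores of at least 100 (89.4), while those near lost regions ended only within 1 kb (19.8 and 48.7), where the C/EBPbeta medians turned, to 0.02 near lost and -0.02 near gained regions. The final calls near gained regions ended within 1 kb and at scores of at least 100, and for C/EBPalpha within 50 kb, and near lost regions only for C/EBPbeta within 50 kb (percentile 21.1), while the middle call near gained C/EBPalpha regions ended at scores of at least 100 (11 genes). The middle calls near lost regions ended within 1 kb (percentiles 8.5 for C/EBPalpha and 76.6 for C/EBPbeta). They also ended at scores of at least 100 (3.3 and 32.0), and held within 50 kb and with either library.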

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

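The tests of low-ranked regions and of low rank alone were chosen after the result was seen. For each of 16 measures over the 8 time points, the gap from the most extreme time to its neighbour was divided by the whole range, and 6 measures had a larger gap than 8 values from a normal distribution usually give. Chance gives about 1 in 20, and time points are not replicates, so a real change with time can give such a gap too.

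The C/EBPalpha list of 48 h had 20061 regions, and the next shortest 25972 (gap over range 0.527). In the C/EBPalpha list of 8 h, 2.92% of regions were 1 bp wide, and 1.25% in the next (0.572). Pol II over Cebpa stood at 6.55 on the log2 scale at 0 h and at most 4.56 later (0.602).

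The C/EBPbeta list of 0 h stood apart in 3 measures: it had 54574 regions against at most 36258 (0.539), a median width of 17 bp against at least 24 (0.778), and 22.3% of regions 1 bp wide against at most 2.31% (0.896). Low rank alone is argued against, since its 20061 top-scoring regions were also met in another list least often (80.5%, others at least 90.6%), and that 37.6% of its 34513 further regions were met (others at least 66.8%, of at most 16197) only restates the excess. Genes near sites of this list alone had lower early Pol II, by -0.07 (1885 genes, percentile 0.0), but so had those of C/EBPalpha at 0, 48 and 168 h (percentiles 0.365, 1.10 and 0.920), so a tie to binding at 0 h stays open. A property of all single-list sites is argued against by percentile 87.1 for the other lists pooled and 99.96 for C/EBPbeta at 3 h. Weaker true sites seen with more signal also stay open, though 23.0% of sites of this list alone lay within 10 kb of a start, 4.92 percentage points above moved ones and below the 32.1% (moved 21.7%) of other single-list sites.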

How the results depend on the processing

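Centres within 100 bp, background set per library, length-matched random lists and rescaling as the main setting, one of 2 planned, were chosen after seeing the data; the cause of the differences below was not tested. At scores of at least 100, which need not mean the same strength in each list, median list lengths were 3648.5 (C/EBPalpha, 28696 in full) and 3934.5 (C/EBPbeta, 32878), the longest list was 4.89 and 10.7 times the shortest (1.56 and 2.65 in full), and the C/EBPbeta to C/EBPalpha length ratio turned to -0.17 (exact permutation p = 0.586). Without pairing by time it stayed 0.22 (exact permutation p = 0.202). Leaving out each time point gave 0.13 to 0.26 for that ratio, 0.232 to 1.30 points for the promoter share, 9.59 to 14.0 points for same-time sharing, -0.26 to -0.0046 (C/EBPalpha) and -0.49 to -0.0558 (C/EBPbeta) for the relation to time, and 0 to 6 genes past the trend test. The C/EBPbeta relation passed only without 3 h (-0.49, exact permutation p = 0.0421). Same-time sharing kept its side of the threshold in each alternative run, and the promoter share never passed it.

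Retention of 0 h regions averaged 26.6% for C/EBPalpha and 18.5% for C/EBPbeta. By overlap of at least 50% of each region it was 12.0% and 8.13%. With the 0 h and the later list both cut to their top 1000 it was 24.7% and 16.7%. By centres within 100 bp, at 20061 regions each, it was 57.7% and 46.6%. Egr1 overlap with C/EBPalpha and C/EBPbeta at 36 h was 25.7% and 22.8%, and 0.0% for both by overlap of at least 50%, since the widths differ, 5.60% and 4.90% in the top 1000, and 42.5% and 43.4% in full lists. Within 5 kb the Egr1 promoter share was 13.2%.

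The limma trend test found 0 genes with no filter (2906 at an unadjusted p under 0.05) and 0 with a pseudocount of 0.05 (602). It found 0 without the 8, 16, 24 or 36 h library (353, 361, 553 and 333) and 6 without 0 h (974). The other alternatives run gave 1. Tests for counts were not run, since the values are not counts.

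Of 92 list windows, 22 to 35 lay outside the central 95% over the alternatives, 24 in the main setting. Without rescaling 4 final medians among these 24 turned: plasma proteins -0.15, drug metabolism -0.23, glucose -0.25 and urea cycle -0.062. With the mean of 0 and 168 h as baseline 5 calls ended, 4 without rescaling, 4 against length-matched random lists and 1 with a pseudocount of 5. With the first or second library of each window alone 4 and 5 ended. Not all of these calls are named here. Of the 176 named genes, each in the window of its largest change, Tagln alone turned, from 0.67 to -0.19 without rescaling, where 25 moved, and 141 moved with a pseudocount of 5. Gained and lost sets outside the central 95% numbered 3 within 1 kb and 5 at scores of at least 100, against 12. C/EBPalpha lost in the middle window turned from -0.01 to 0.0677 (50 kb), 0.0132 (1 kb), 0.0166 (scores of at least 100) and 0.0151 (either library). Within 1 kb, C/EBPalpha gained in the final window turned to 0.0132, and C/EBPbeta gained and lost early to -0.0222 and 0.0169. Unknown depth limits what absent regions mean.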

Other observations

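The tests of Egr1 coordinates and weak Egr1 peaks, of the order of the libraries, of background at 3 h, and of later libraries as the reference were chosen after the results were seen. Genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, had higher Pol II early (median log2 change 0.78, percentile 99.8) and in the middle window (1.08, percentile 99.98). At 16 h the median was 1.67, and 11 of 16 were higher by 1 or more. Creld2 was at 0.478 at 0 h and 14.4 at 16 h, Hyou1, a chaperone gene, at 1.80 and 9.01, and Manf, called Armet in the files, at 1.01 and 8.81. The members differed. Early 5 were higher and 3 lower by 1 or more, and in the middle window 8 and 2. Trib3 had an early log2 change of -3.02. In the final window 1 was higher and 5 lower, among them Hyou1 (-2.20) and Dnajb9 (-2.09). The late and final medians were 0.13 and 0.01, inside the central range, and so were those of 3 h alone (0.36) and 24 h alone (0.31). At an unadjusted p under 0.05 of limma's trend test there were 6 of 14 tested members, and none passed when adjusted over the list alone. From 6 to 12 of 16 had a C/EBP region within 1 kb over the 16 lists, where 17.6% to 37.8% of all genes tested for Pol II had one.

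Circadian clock genes had lower Pol II in the early, middle and late windows, with medians of -0.39, -0.32 and -0.43 (percentiles 0.59, 0.42 and 0.09), and -0.06 in the final one (percentile 8.26). Of 16 members, 5, 3 and 5 were lower by 1 or more in the early, middle and late windows, and 1, 0 and 0 higher. The early placement ended with the mean of 0 and 168 h as baseline and with the 3 h library alone (percentile 2.5). Bhlhe41 was 1.48 higher early and Per1 0.36 higher, and Per1 stood at -1.85 in the final window. Nr1d1, a repressor of the clock, was at 32.5 at 0 h, 0.0704 at 16 h and 18.7 at 168 h. Dbp, a clock output gene, was at 57.6, 11.3 and 30.8, and its neighbour Sphk2 at 104, 6.35 and 47.4. The time of day of each sample is not given in the sources used here. An Egr1 peak lay within 10 kb of the start of Per1, Per2, Per3, Cry1, Cry2, Nr1d1 and Bhlhe41.

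The 121 genes of the metabolic lists together had a median early change of -0.19 (percentile 0.94), -0.66 at 3 h and 0.00 at 8 h. Gene length alone is argued against by lists matched on it (percentile 0.30), and the 0 h library alone by percentiles of 0.0 against each of the 24, 36, 48 and 168 h libraries, with and without rescaling. The size of the change against 168 h decides nothing, since -0.76 became -0.30 without rescaling, which had moved that library by 0.97. Background that differed between libraries left -0.58 at 3 h once set per library, and for the early window it gave -0.15, which decides nothing, since the bound set beforehand lay below the uncorrected value. Lower polymerase on these genes at 3 h stays a hypothesis, with the 3 h library, whose summed signal stood apart, its single source.

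Egr1 peaks had a low promoter share, 4.54%. Another build or an offset is argued against by an overlap with C/EBP lists 9.17 times that of moved peaks, weak peaks by 4.45% in the 2474 top-scoring peaks (lowest C/EBP list 7.54%), and wide peaks by 6.30% that come within 1 kb at all, against at least 9.88% of C/EBP regions widened alike. Signal over highly transcribed genes is argued against by 1.82% of peak centres in the bodies of the top 5% of genes by Pol II, with 3.63% and 4.21% for C/EBPalpha and C/EBPbeta at 36 h. The design names no group that could give a biological explanation, and none was tested.

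Of 100 orders of the libraries, the real one included, 4 gave as many genes past the trend test as the real order (1 gene). This lies close to the limit, a share of 0.05 set after the result was seen, so chance order is not excluded. The count was 0 without the 8, 16, 24 or 36 h library and 6 without 0 h. The highest other order gave 22 genes, several times the real count, and why it did so was not tested. At an unadjusted p under 0.05, 15 of 100 orders gave as many as the real 465, so chance is not excluded for that count.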
